A study of Arabis alpina with 23 samples.

How the data were processed

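The series measured transcripts in Arabis alpina, a perennial relative of Arabidopsis, in the Pajares accession. Per the labels, very young axillary buds (AB), each with a single leaf primordium, and the shoot apical meristem (SAM), taken with 1 leaf primordium, were dissected from plants at 4 stages. Stage 1 was 4 weeks of growth, stage 2 was 8 weeks, and stages 3 and 4 followed 4 and 7 weeks of cold at 4 °C. Each biological replicate pooled 120 to 150 buds or meristems, per the labels. There were 23 libraries, 3 for each tissue and stage except AB stage 1, which had 2. Per the labels' protocols, RNA was extracted with a plant total RNA kit with DNase on the column and sequenced as single-end reads of 150 bp.

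The deposited table gives for each gene the count of total mapped reads per library, per the file headers. It also holds TPM values, which sum to the same total in each library and were computed by the authors. The deposited log2 fold changes and false discovery rate p-values belong to 4 comparisons made by the authors. They were used only for a count of genes beside the counts computed here. A further 6 columns of authors' comparisons carry no label and were not used. Another 46 columns of values by library, counted over all 23 libraries, were not used either. The deposited annotation gives the gene coordinates of the version 5 assembly. Per the file headers, its gene models were moved from version 4 by alignment of proteins. The submitters' processing notes name only FastQC, and the aligner, the counting tool and the use of strand were not given in the sources used here. Reads from overlapping genes on opposite strands therefore cannot be told apart. A reference genome was not used here.

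All 34220 gene identifiers in the table matched the annotation. An informative description was given for 21500 genes. A gene model was placed at more than 1 locus for 4750 genes, and such copies can share reads, so their values are uncertain. Coding lengths were multiples of 3 for 99.5% of the models, so the lengths hold no untranslated regions. Gene symbols were assigned from the descriptions in the files, since the files do not pair the genes with Arabidopsis locus codes. Several genes can share a description, so a symbol may belong to a close relative of the named gene. BRC1, SPL15, COR15A and CYCB1-1 could not be paired with a gene, and TFL1 was paired with a gene too low in counts to be tested. FUL was paired with 2 genes, of which 1 was tested. VIN3 was paired with a gene (Aa_G183140) described as vernalization insensitive 3-like, so results given for VIN3 may belong to a close relative. The tested FUL model has a coding length of 213 bp and the FLC model 180 bp.

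Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 21414 genes. Libraries were scaled by TMM, and CPM values are counts per megaread of the scaled library size. A model with 1 coefficient for each tissue and stage was fitted to all 23 libraries with robust dispersion estimates. The quasi-likelihood F test was used with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 12 comparisons were AB against SAM at each stage and over the mean of the 4 stages, the 3 steps between successive stages in each tissue, and the interaction of tissue and stage. Changes are on the log2 scale with the standard error (SE) of the fit, which was taken from the change and the F statistic. Levels are mean CPM ± SD. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts no fold is given. Floors cover counting error only.

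Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. Adjustment was over 23 lists and 11 comparisons, 253 tests together. An estimated correlation was the alternative. The 24 lists were meristem maintenance, boundary and axillary meristem initiation, bud dormancy and branching control, strigolactone, auxin, cytokinin, gibberellin and abscisic acid pathways, floral repressors, vernalization, floral integrators and age pathway, floral meristem and organ identity, cold acclimation, DNA replication, mitosis, cell cycle inhibitors, leaf polarity and growth, circadian clock, wounding and jasmonate, photosynthesis (leaf mesophyll markers), and vascular, trichome, stomatal lineage and shoot epidermis markers. The last 5 and floral identity served as markers of cells that a dissected sample could also hold. In all, 353 genes matched a list. Counts of list members called stand beside the share of all tested genes called in that comparison. For AB against SAM this share was 32.8%, 37.4%, 44.2% and 3.47% at stages 1 to 4 and 52.9% over their mean. For the successive steps it was 1.16%, 22.2% and 47.3% in AB and 7.58%, 24.3% and 9.18% in SAM. A count near that share does not set a list apart. The bud dormancy and branching control list held only genes paired with DIN10, DRM, DRM1, SEN1 and NCED. None of the BRC and HB genes meant for it could be paired from the descriptions. Such genes may still have been measured under other descriptions, so nothing is said here on their levels. The list's NCED genes also belong to the abscisic acid list. The strigolactone list had 1 tested member and was not tested as a list.

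The groups, comparisons, lists, tests, rule for named genes and most alternatives were chosen before the data were examined. Under that rule 17 genes are always considered (STM, WUS, CLV3, LAS, CUC2, RAX1, BRC1, FLC, TFL1, SOC1, FUL, LFY, AP1, SPL15, VIN3, COR15A and CYCB1-1). Each comparison adds the 5 largest rises and falls past the threshold with a mean of at least 5 CPM in the higher group and no overlap between libraries, and up to 4 members of each list with the smallest adjusted p. The interaction adds the 5 smallest p-values and up to 10 list members. The robust option of the fit, the tests of differences between steps, comparisons across stages, overlaps of gene sets, heat shock genes and families sharing a description were chosen after the data had been examined.

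The labels name no batch and do not say whether equal replicate numbers pair an AB with a SAM library. Deviations from the group means, correlated across genes between equally numbered libraries, were 0.155 to 0.254 at stage 2 and 0.134 to 0.190 at stage 3, all above the bound of 0.1 set for pairing. They were −0.0437 to 0.0584 at stage 1 and −0.115 to 0.212 at stage 4. A replicate block was therefore an alternative, and its values are given beside the counts of stages 2 and 3.

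Total counts ran from 12.2 M (megareads) to 26.2 M per library. On simulated counts for 20895 genes, with 200 changed, the test at the AB against SAM sizes of stage 2 recovered 50.7% of 1.5-fold, 79.1% of 2-fold and 95.5% of 4-fold changes, with 6 false calls among 156. For AB stage 1 to 2 these shares were 46.3%, 80.6% and 92.4%, with 5 false calls among 151. Simulated counts with no change at the stage 3 sizes gave 0 calls by edgeR. The 200 simulated changes lay in AB stage 2 only and went in either direction at random. The real comparison at stage 2 called 8014 of 21414 genes, with 2090 at least 2-fold higher and 496 at least 2-fold lower in AB. Recovery and false calls may therefore differ there. The list test called 5 of 100 unchanged lists at an unadjusted 0.05. The simulated genes varied independently of one another, so this does not test the preset correlation on real lists.

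Alternatives were RLE scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2 TPM with pseudocounts of 1 and 0.1, a 2-fold minimum, the groups compared alone, the replicate block, and leaving out each library. A block fitted to the 6 libraries compared, thinning of all libraries to the shallowest, and leaving out the shallowest and the deepest library were added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.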

Results

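Transcripts were counted in axillary buds (AB) and shoot apical meristems (SAM) of the perennial Arabis alpina at 4 stages, which are 4 weeks of growth (stage 1), 8 weeks (stage 2), and 4 and 7 weeks of cold (stages 3 and 4). Each group had 3 libraries, except AB stage 1 with 2. Total counts, in megareads (M), were 13.97 to 14.1 M in AB stage 1, 14.1 to 14.5 M in AB stage 2, 14.2 to 14.8 M in AB stage 3 and 15.3 to 15.7 M in AB stage 4. In the SAM they were 18.1 to 18.7 M at stage 1, 16.3 to 18.6 M at stage 2, 12.2 to 18.2 M at stage 3 and 18.3 to 26.2 M at stage 4. AB libraries averaged 14.6 ± 0.619 M (SD, n = 11) and SAM libraries 18.1 ± 3.18 M (n = 12). Between 21824 and 23524 genes were detected per library. The 10 most abundant genes took 2.26% to 3.0% of the counts. The first principal component held 48.4% of the variance and the second 17.1%.

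**Figure D1:**
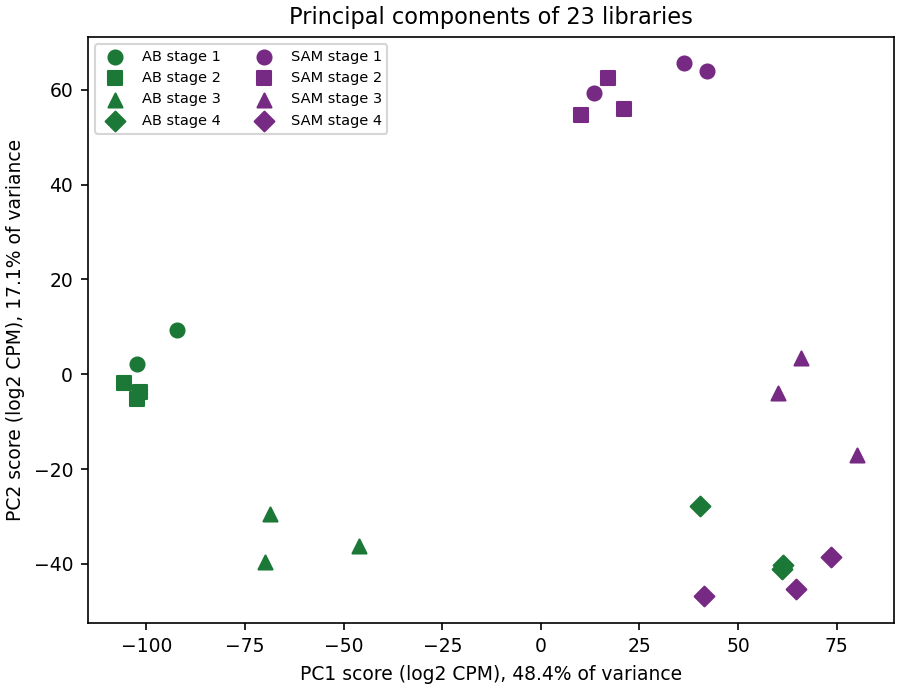
Each point is 1 of the 23 libraries placed by the first (x axis, 48.4% of variance) and second (y axis, 17.1%) principal component of log2 CPM, with AB in green, SAM in purple and a shape for each stage. AB of stages 1 to 3 lie apart from SAM, and AB stage 4 replicates 2 and 3 lie among SAM stage 4, with replicate 1 outside them on both axes (40.3 and −27.9).

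The first question was how a bud forming at a distance from the SAM differs from the SAM itself in young plants of stage 1. A cytokinin oxidase (CKX, Aa_G188410), which degrades cytokinin, stood at 84.1 ± 16.2 CPM in AB and 1.31 ± 0.396 in SAM, a difference of 6.0 ± 0.34 on the log2 scale (SE, n = 2 and 3, adjusted p = 2.31e-09, edgeR with Benjamini-Hochberg adjustment). A gibberellin 2-oxidase (GA2OX, Aa_G655020), which inactivates gibberellin, was higher by 4.99 ± 0.31, and the boundary gene LOB (Aa_G320940) by 4.38 ± 0.27 (40.3 ± 9.37 against 1.93 ± 0.599 CPM). The stem cell regulator WUS (Aa_G197460) was higher by 2.01 ± 0.37 and RAX1 (Aa_G583140), which promotes axillary meristem formation, by 1.82 ± 0.33. LFY (Aa_G61540), a floral meristem identity gene on chromosome 8 (46457059 to 46459751), was lower in AB, with a difference of −2.08 ± 0.31 (adjusted p = 2.77e-05).

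Across the hormone lists at stage 1, 8 of 23 auxin genes were higher in AB and 2 lower (9 and 2 adjusted over the list alone). Among them, the auxin-induced genes IAA19 (Aa_G424060, 4.73 ± 0.48) and IAA2 (Aa_G518850, 3.92 ± 0.47) were higher. Of 19 gibberellin genes 8 were higher and 2 lower (9 and 2 adjusted over the list alone; camera adjusted p = 0.0378, adjusted p = 0.644 with an estimated correlation). GA20OX (Aa_G598100), a gibberellin synthesis gene, had 18.4 ± 2.70 CPM in AB and 1 count in SAM. Cytokinin genes went both ways, with 5 of 21 higher and 9 lower (6 and 9 adjusted over the list alone), and a second CKX (Aa_G198500) differed by −3.29 ± 0.27. In bud dormancy and branching control, a list here without BRC1, 5 of 10 were higher and 1 lower. Among them was DRM1 (Aa_G438760, 3.97 ± 0.62), a dormancy-associated gene. In boundary and axillary meristem initiation 4 of 7 were higher and 1 lower, and in floral repressors 3 of 22 were higher and 5 lower.

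Genes of DNA replication and photosynthesis were lower in AB at stage 1. Of 17 DNA replication genes 9 were lower (10 adjusted over the list alone), with a median of −0.35 (camera adjusted p = 0.00133, adjusted p = 0.644 with an estimated correlation). The replication licensing gene MCM5 (Aa_G194540) differed by −0.41 ± 0.09 and the D-type cyclin CYCD3 (Aa_G165790) by −1.0 ± 0.13. Of 23 photosynthesis genes 14 were lower and 1 higher (median −0.67, adjusted p = 2e-05, adjusted p = 0.644 with an estimated correlation), and LHCB4 (Aa_G53980) stood at 494 ± 26.9 against 1004 ± 27.2 CPM. In leaf polarity and growth 8 of 20 were lower and 4 higher, including GRF2 (Aa_G389580, −1.0 ± 0.11). Meristem maintenance had 4 of 14 higher and 2 lower (4 and 3 adjusted over the list alone), and ATH1 (Aa_G58550), a homeobox gene, differed by −1.70 ± 0.14. Among other markers, 4 of 10 vascular genes were higher and 2 lower, with the phloem sucrose transporter SUC2 (Aa_G371930) higher by 4.84 ± 0.69. For trichome markers the counts were 1 of 5 higher and 1 lower, and for shoot epidermis markers 2 of 7 higher and 1 lower.

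Among all genes at stage 1, 7016 of 21414 passed the threshold, 3899 higher and 3117 lower in AB, and 9020 had an unadjusted p under 0.05. The 2 groups of libraries did not overlap for 6935 of the 7016, which were chosen for differing. Over all 21414 genes tested they did not overlap for 12173, where chance gives 20% for 2 against 3 libraries. A cytochrome p450 gene (Aa_G83220) was at least 125-fold higher in AB (6.91 ± 0.216 CPM against 0), and a phenylalanine ammonia-lyase (Aa_G338680) stood at 5.08 ± 0.211 CPM in AB and 187 ± 13.5 in SAM. STM (Aa_G408930, −0.29 ± 0.13), CLV3 (Aa_G155810, 0.18 ± 0.44), LAS (Aa_G193190, −0.10 ± 0.26), FLC (Aa_G579940, −0.17 ± 0.22) and SOC1 (Aa_G15970, 0.15 ± 0.25) did not pass. Calls for CUC2 (Aa_G141220, −0.58 ± 0.20, adjusted p = 0.0277) and VIN3 (Aa_G183140, −0.24 ± 0.08, adjusted p = 0.0267) were lost under 7 and 8 alternatives, where adjusted p reached 0.181 and 0.227. For CUC2 leaving out any of the 5 libraries ended the call, and for VIN3 leaving out either AB library or SAM stage 1 replicate 1 or 2 did. Without AB stage 1 replicate 2 the count of genes was 4347. On TPM with a pseudocount of 1 the split was 4377 higher and 2233 lower.

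At stage 2 the same comparison asked whether the contrast of bud and apex held in older plants. CKX (Aa_G188410) was again higher in AB, by 6.70 ± 0.35 (SE, n = 3 and 3, 84.0 ± 11.7 against 0.807 ± 0.191 CPM, edgeR adjusted p = 7.25e-10). GA2OX (Aa_G655020) was higher by 5.39 ± 0.30, LOB (Aa_G320940) by 3.5 ± 0.23 and WUS (Aa_G197460) by 1.81 ± 0.33. CYP707A (Aa_G290950), which degrades abscisic acid, was higher by 6.38 ± 0.72. LFY (Aa_G61540) differed by −1.97 ± 0.25, ATH1 (Aa_G58550) by −1.60 ± 0.12 and the boundary gene CUC2 (Aa_G141220) by −1.25 ± 0.18.

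By list at stage 2, gibberellin had 8 of 19 higher and 3 lower (9 and 3 adjusted over the list alone; camera adjusted p = 0.0406, adjusted p = 0.644 with an estimated correlation). Auxin had 10 of 23 higher and 7 lower (13 and 7 adjusted over the list alone), including IAA2 (Aa_G518850, 4.15 ± 0.45), and cytokinin 6 of 21 higher and 9 lower (6 and 11 adjusted over the list alone). Dormancy and branching had 3 of 10 higher and 1 lower (4 and 1 adjusted over the list alone), with a DRM1 gene (Aa_G430660) at 126 ± 46.3 against 27.8 ± 7.67 CPM. DNA replication had 10 of 17 lower (11 adjusted over the list alone), with a median of −0.37 (adjusted p = 0.00133, adjusted p = 0.644 with an estimated correlation) and CYCD3 (Aa_G97330) at −0.84 ± 0.09. Photosynthesis had 11 of 23 lower (13 adjusted over the list alone; median −0.39, adjusted p = 0.000987, adjusted p = 0.780 with an estimated correlation). Mitosis genes were lower in 6 of 19 and higher in 1. Wounding and jasmonate genes were higher in 3 of 10 and lower in 2, and vascular markers higher in 4 of 10 and lower in 3.

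Of all genes at stage 2, 8014 passed, 4251 higher and 3763 lower. Libraries did not overlap for 7478 of these, which were chosen for differing. Over all 21414 genes tested they did not overlap for 9847, where chance gives 10% for 3 against 3. With the replicate block 8011 genes passed the threshold, and 8511 with the block fitted to these 6 libraries. A beta glucosidase gene (Aa_G784430) was at least 292-fold higher in AB (16.3 ± 1.03 CPM against 0). Of the genes higher at stage 1, 3154 were also higher at stage 2, where chance overlap gives 774, and 2238 were lower at both, where chance gives 548. RAX1 (Aa_G583140, 0.54 ± 0.29), STM (Aa_G408930, −0.28 ± 0.12), CLV3 (Aa_G155810, 0.20 ± 0.42), FLC (Aa_G579940, −0.23 ± 0.20), SOC1 (Aa_G15970, −0.21 ± 0.21) and VIN3 (Aa_G183140, −0.18 ± 0.07) did not pass. LAS (Aa_G193190, −0.58 ± 0.23, adjusted p = 0.0494) lost its call under 12 alternatives, the leaving out of any of the 6 libraries among them, and its adjusted p reached 0.233.

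At stage 3, after 4 weeks of cold, the comparison asked how bud and apex differed during cold. LFY (Aa_G61540) stood at 2.11 ± 0.256 CPM in AB and 19.8 ± 4.89 in SAM, a difference of −3.24 ± 0.22 (SE, n = 3 and 3, edgeR adjusted p = 3.56e-09). FUL (Aa_G862480, chromosome 8, 45918358 to 45918725), which promotes flowering, was at 0.225 ± 0.0341 against 14.3 ± 10.1 CPM (adjusted p = 1.92e-05), and SPL4 (Aa_G381970) of the age pathway differed by −6.91 ± 0.81. The cytokinin response regulators type-A ARR (Aa_G238700) and ARR5 (Aa_G561390) were higher in AB by 4.14 ± 0.27 and 3.35 ± 0.24. MAX3 (Aa_G175240), a strigolactone synthesis gene and the list's only tested member, was at least 116.6-fold higher (7.75 ± 1.70 CPM against 0).

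By list at stage 3, gibberellin had 11 of 19 higher (camera adjusted p = 0.00809, adjusted p = 0.613 with an estimated correlation). Abscisic acid had 12 of 17 higher and 2 lower (adjusted p = 0.0534), auxin 13 of 23 higher and 6 lower, cytokinin 9 of 21 higher and 6 lower, and floral repressors 10 of 22 higher and 2 lower. Floral integrators and age pathway had 3 of 10 higher and 5 lower (adjusted p = 0.0938), and floral identity had 3 of 6 lower (adjusted p = 0.0550). In dormancy and branching 6 of 10 were higher and 1 lower (7 and 2 adjusted over the list alone), including NCED (Aa_G56170), an abscisic acid synthesis gene, at 5.18 ± 1.22, and DRM1 (Aa_G430660) at 262 ± 87.0 against 56.04 ± 34.3 CPM. DNA replication had 14 of 17 lower (median −0.61, adjusted p = 1.5e-05, adjusted p = 0.613 with an estimated correlation), with the polymerase clamp PCNA (Aa_G275760) at −0.85 ± 0.11 and MCM3 (Aa_G206370) at −0.68 ± 0.10. Photosynthesis had 10 of 23 lower (median −0.29, adjusted p = 0.0111, adjusted p = 0.841 with an estimated correlation), and leaf polarity and growth 10 of 20 lower and 3 higher, with GRF5 (Aa_G116360) at −2.16 ± 0.19. Vascular markers had 5 of 10 higher and 3 lower (6 and 3 adjusted over the list alone).

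Of all genes at stage 3, 9460 passed, 4726 higher and 4734 lower. Libraries did not overlap for 8775 of these, which were chosen for differing, and for 10894 of all 21414 genes tested (chance 10%). With the replicate block 9452 genes passed the threshold, or 7710 when it was fitted to these 6 libraries. On TPM with a pseudocount of 1 there were 5425 higher and 3485 lower. WUS (Aa_G197460) was higher by 1.06 ± 0.33 (adjusted p = 0.0123), a call that ended without SAM stage 3 replicate 1, where adjusted p was 0.0816 (alternatives ranged from 0.00115 to 0.0816). RAX1 (Aa_G583140, −0.78 ± 0.30, adjusted p = 0.0406) and VIN3 (Aa_G183140, −0.20 ± 0.07, adjusted p = 0.0319) lost their calls under 11 and 14 alternatives, with adjusted p up to 0.323 and 0.2001. Each was lost without AB stage 3 replicate 1 or 2 or SAM stage 3 replicate 3, RAX1 also without AB replicate 3, and VIN3 also without SAM replicate 1 or 2. STM, CUC2, LAS, CLV3, FLC and SOC1 did not pass.

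At stage 4, after 7 weeks of cold, the comparison asked how far buds still differed from the SAM as flowering genes came on. Some floral identity genes were lower in AB. AP1 (Aa_G283230, chromosome 2, 23713656 to 23717789) stood at 1.74 ± 0.600 against 33.8 ± 15.9 CPM, SEP4 (Aa_G675730) at 3.48 ± 1.12 against 19.5 ± 8.05, and LFY (Aa_G61540) at 37.0 ± 6.63 against 137 ± 27.4. For LFY the difference was −1.89 ± 0.16 (SE, n = 3 and 3, edgeR adjusted p = 1.84e-06). The floral repressor FLC (Aa_G579940, chromosome 8, 6184468 to 6185945) was higher in AB by 1.74 ± 0.26 (3.64 ± 0.358 against 1.07 ± 0.225 CPM, adjusted p = 0.000484). A cyc-like protein 1 gene (Aa_G395870) was higher by 4.48 ± 0.47 and CKX (Aa_G188410) by 3.70 ± 0.43. FUL (Aa_G862480), at 35.6 ± 9.11 against 43.4 ± 2.49 CPM, did not pass (adjusted p = 0.754).

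By list at stage 4, floral meristem and organ identity had 3 of 6 lower (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 6.55e-09, adjusted p = 0.0841 with an estimated correlation). Photosynthesis had 5 of 23 lower (12 adjusted over the list alone; median −0.34, adjusted p = 2.55e-08, adjusted p = 0.614 with an estimated correlation), including PSAH (Aa_G568100, −0.70 ± 0.11). Cytokinin had 4 of 21 higher (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.00984, adjusted p = 0.311 with an estimated correlation). Boundary genes had 1 of 7 higher (3 adjusted over the list alone; adjusted p = 0.0276, adjusted p = 0.613 with an estimated correlation), which was LOF1 (Aa_G254960, 0.72 ± 0.13). Meristem maintenance had 3 of 14 lower, among them genes described as the receptor kinase CLV1 (Aa_G590900, −0.89 ± 0.09, and Aa_G201460, −1.04 ± 0.16). The shared description does not settle which gene, if either, is CLV1 itself. Cold acclimation had 1 of 10 lower (3 adjusted over the list alone; adjusted p = 0.0162, adjusted p = 0.613 with an estimated correlation), which was ERD7 (Aa_G122460, −1.04 ± 0.12). Vascular markers had 1 of 10 lower (3 adjusted over the list alone; adjusted p = 0.00518, adjusted p = 0.461 with an estimated correlation). DNA replication had 0 of 17 called by edgeR, 4 at an unadjusted p under 0.05 and 1 by DESeq2, with a median of 0.12 (adjusted p = 0.0327, adjusted p = 0.815 with an estimated correlation).

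Of all genes at stage 4, 743 passed, 290 higher and 453 lower, and 3485 had an unadjusted p under 0.05. Libraries did not overlap for 739 of the 743, which were chosen for differing, and for 5734 of all 21414 genes tested (chance 10%). Without AB stage 4 replicate 1 or 2 or SAM stage 4 replicate 2 or 3 the count of genes past the threshold was 377, 373, 437 and 383. DESeq2 gave 1140 and the 6 libraries alone 1465. The AP1 call (adjusted p = 0.00352) was lost with DESeq2, where adjusted p was 0.723 (alternatives from 2.83e-08 to 0.723). STM, WUS, CLV3, LAS, CUC2, RAX1, SOC1 and VIN3 did not pass. The median size of the AB against SAM difference over all tested genes was 0.271, 0.265, 0.307 and 0.135 on the log2 scale at stages 1 to 4.

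**Figure D2:**
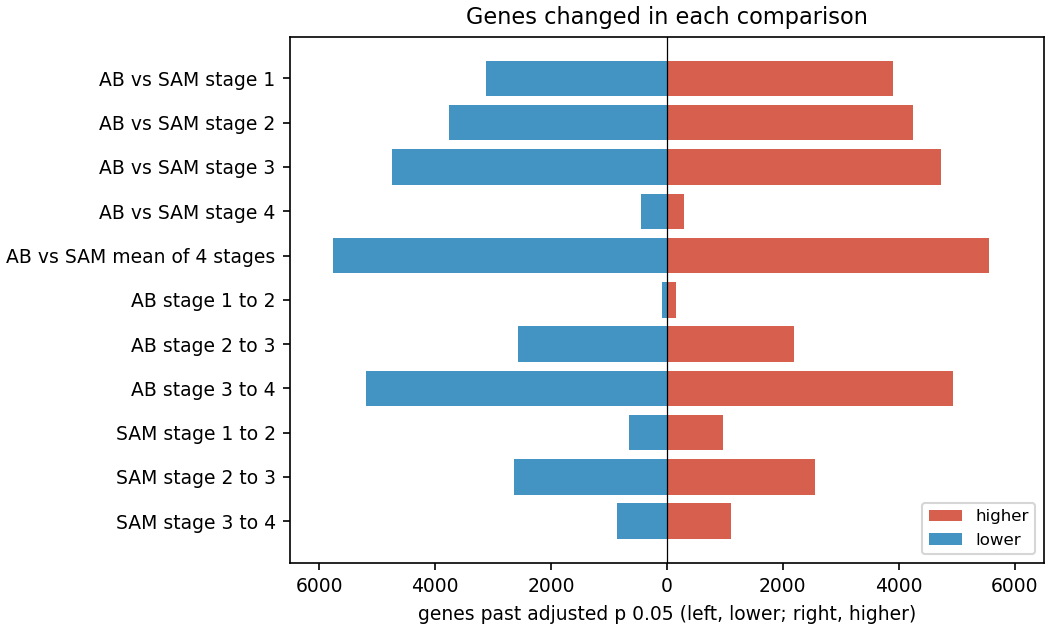
Horizontal bars give the number of genes past the threshold in each comparison (x axis, genes), higher to the right and lower to the left. AB against SAM had 7016, 8014, 9460 and 743 genes at stages 1 to 4.

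The mean of the 4 stages asked what separated bud and SAM on average over the stages. The cyc-like protein 1 gene (Aa_G395870) averaged 64.03 CPM in AB and 0.412 in SAM, a difference of 7.0 ± 0.23 (SE, n = 11 and 12, edgeR adjusted p = 4.43e-13). A homeodomain gene (Aa_G147020) was higher by 6.96 ± 0.33, CKX (Aa_G188410) by 5.80 ± 0.19, GA2OX (Aa_G655020) by 3.40 ± 0.14, LOB (Aa_G320940) by 3.28 ± 0.13 and WUS (Aa_G197460) by 1.28 ± 0.17. LFY (Aa_G61540) differed by −2.29 ± 0.12, CUC2 (Aa_G141220) by −0.62 ± 0.09 and the meristem gene STM (Aa_G408930) by −0.27 ± 0.06. FLC (Aa_G579940) was higher by 0.40 ± 0.12 as the mean of log2 differences, although its mean CPM was 8.11 in AB and 8.30 in SAM. In all, 11320 genes passed, 5554 higher and 5766 lower, and on TPM with a pseudocount of 1 there were 6561 higher and 4539 lower.

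By list over the mean of stages, photosynthesis had 16 of 23 lower (median −0.43, camera adjusted p = 2e-05, adjusted p = 0.644 with an estimated correlation), and LHCB4 (Aa_G53980) differed by −0.60 ± 0.05. DNA replication had 15 of 17 lower (median −0.30, adjusted p = 0.000236, adjusted p = 0.644 with an estimated correlation), gibberellin 10 of 19 higher and 3 lower (11 and 4 adjusted over the list alone; adjusted p = 0.0276, adjusted p = 0.644 with an estimated correlation), and floral identity 2 of 6 lower (adjusted p = 0.00592, adjusted p = 0.613 with an estimated correlation). Cell cycle inhibitors had 3 of 10 higher and 3 lower. Circadian clock genes had 1 of 7 higher (none adjusted over the list alone), while at single stages 0 of 7 passed by edgeR, with 1 at stage 3 at an unadjusted p under 0.05 and by DESeq2 and limma-trend. Stomatal lineage markers had 0 of 3 called by edgeR, unadjusted or by DESeq2 and limma in any of the 12 comparisons.

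The interaction asked whether the difference of bud and SAM changed with stage. It passed for 7295 of the 21414 genes tested (34.1%) by edgeR, the share beside which the list counts below stand. CKX (Aa_G198500), GA2OX (Aa_G655020), LOB (Aa_G320940), ATH1 (Aa_G58550) and a gene described as CLV1 (Aa_G590900) were among the genes that passed. By list it passed for 15 of 17 DNA replication genes, 17 of 23 auxin (18 adjusted over the list alone), 16 of 21 cytokinin (18 adjusted over the list alone), 11 of 23 photosynthesis and 6 of 14 meristem maintenance genes. Of 7 circadian clock, 7 shoot epidermis and 3 stomatal lineage genes 0 passed by edgeR, DESeq2 or limma, and 1 epidermis gene had an unadjusted p under 0.05.

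Steps between stages asked how each tissue changed as plants aged and passed through cold. From stage 1 to 2, AB changed little. A cytochrome p450 gene (Aa_G67080) fell by 3.91 on the log2 scale (SE 0.45, n = 3 and 2, from 18.9 ± 1.89 to 1.25 ± 0.444 CPM, edgeR adjusted p = 0.000157). The photosynthesis gene GAPA (Aa_G25630) fell by 0.64 (SE 0.12, adjusted p = 0.0116), a call lost without AB stage 1 replicate 1 or AB stage 2 replicate 1, where adjusted p reached 0.215 (alternatives from 0.000248). Abscisic acid genes had 0 of 17 called by edgeR and DESeq2, 1 by limma-voom and 9 at an unadjusted p under 0.05, and the list tested higher (camera adjusted p = 0.00102, adjusted p = 0.613 with an estimated correlation). Photosynthesis had 2 of 23 lower (3 adjusted over the list alone; adjusted p = 0.00200, adjusted p = 0.794 with an estimated correlation), floral integrators and age pathway 1 of 10 higher (2 adjusted over the list alone; adjusted p = 0.0202, adjusted p = 0.644 with an estimated correlation), and wounding and jasmonate 0 of 10 by edgeR, 3 unadjusted and 1 by DESeq2 (2 higher adjusted over the list alone; adjusted p = 0.0121, adjusted p = 0.613 with an estimated correlation). DNA replication and mitosis tested lower as sets (adjusted p = 0.00515 and 0.0380, adjusted p = 0.702 for both with an estimated correlation), with 0 of 17 and 0 of 19 called by edgeR, 4 and 4 at an unadjusted p under 0.05, and 0 and 1 by DESeq2 (0 by limma-voom and limma-trend; 2 mitosis genes lower adjusted over the list alone). In all 249 genes passed, 159 higher and 90 lower, and 2809 had an unadjusted p under 0.05. Without AB stage 1 replicate 1 the count was 29, without AB stage 2 replicate 1 it was 57, and with AB of these stages alone 140, while DESeq2 gave 405 and limma-trend on TPM 407. None of the always-considered genes passed.

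From stage 1 to 2 the SAM gained the MADS gene AGL42 (Aa_G131050), which rose by 1.71 ± 0.19 (SE, n = 3 and 3, 5.21 ± 1.99 to 17.1 ± 1.70 CPM, edgeR adjusted p = 2.74e-05). A gene described as PIF6 (Aa_G2440) rose by 4.11 ± 0.67 and a trehalose-6-phosphate phosphatase gene (Aa_G197880) fell by 4.76 (SE 1.02). Photosynthesis genes fell, 8 of 23 (11 adjusted over the list alone; median −0.37, camera adjusted p = 5.27e-09, adjusted p = 0.613 with an estimated correlation), including PSBO (Aa_G113230, −0.57 ± 0.09). Floral integrators and age pathway rose in 3 of 10 (6 adjusted over the list alone; adjusted p = 0.000389, adjusted p = 0.613 with an estimated correlation). Dormancy and branching rose in 2 of 10 (adjusted p = 0.00713, adjusted p = 0.614 with an estimated correlation), and cold acclimation in 2 of 10 (3 adjusted over the list alone; adjusted p = 0.0111, adjusted p = 0.613 with an estimated correlation). DNA replication tested lower, with 1 of 17 lower (adjusted p = 0.00647, adjusted p = 0.706 with an estimated correlation), and abscisic acid higher, with 2 of 17 higher (adjusted p = 0.0468, adjusted p = 0.702 with an estimated correlation). In all 1623 genes passed, 967 higher and 656 lower, and on TPM with a pseudocount of 1 there were 1162 higher and 405 lower. Without SAM stage 1 replicate 1 or 2 or SAM stage 2 replicate 1 or 3 the count was 554, 613, 725 and 1072. SOC1 (Aa_G15970, 0.66 ± 0.21, adjusted p = 0.0575) and the other always-considered genes did not pass. Of the 159 genes that rose in AB, 64 rose in SAM too, where chance gives 7.18. AB and SAM differed in this step for 21 genes.

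From stage 2 to 3, into the cold, FLC (Aa_G579940) fell in both tissues, from 14.01 ± 1.88 to 3.1 ± 1.06 CPM in AB (−2.17 ± 0.22, SE, n = 3 and 3, edgeR adjusted p = 3.56e-06) and from 16.4 ± 1.11 to 2.51 ± 0.995 in SAM (−2.67 ± 0.23, adjusted p = 1.34e-07). SOC1 (Aa_G15970), a floral integrator on chromosome 4 (51263979 to 51266537), rose by 1.29 ± 0.20 in AB and 1.29 ± 0.19 in SAM. LFY (Aa_G61540) rose by 1.68 ± 0.19 in SAM, while in AB its change was 0.42 ± 0.30 (adjusted p = 0.352), and the tissues differed by −1.27 ± 0.36 in this step (adjusted p = 0.0494). FUL (Aa_G862480) went from 1 count over the 3 libraries to 14.3 ± 10.1 CPM in SAM (adjusted p = 2.72e-05). In the cold acclimation list 2 of 10 rose in AB and 4 of 10 in SAM (camera adjusted p = 0.474 and 0.0649), with COR27 (Aa_G595780) up by 2.21 ± 0.35 in AB and 2.53 ± 0.37 in SAM, and COR15B (Aa_G574060) at 16.9 ± 8.18 against 0.138 ± 0.181 CPM in AB.

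In AB from stage 2 to 3, dormancy and branching rose in 5 of 10 and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00422, adjusted p = 0.613 with an estimated correlation), including SEN1 (Aa_G376370, 2.27 ± 0.39). Abscisic acid genes rose in 6 of 17 and fell in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.0274, adjusted p = 0.644 with an estimated correlation), including ABF3 (Aa_G274240, 1.00 ± 0.15). Photosynthesis rose in 6 of 23 (8 adjusted over the list alone; adjusted p = 0.00575, adjusted p = 0.816 with an estimated correlation). CKX3 (Aa_G197800) fell by 3.33 (SE 0.31). In all 4764 genes passed in AB, 2190 higher and 2574 lower, and 2765 with AB of these stages alone.

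In SAM from stage 2 to 3, cytokinin genes fell in 10 of 21 and rose in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.000294, adjusted p = 0.0841 with an estimated correlation), among them ARR5 (Aa_G561390, −2.42 ± 0.24) and CKX (Aa_G273140, −2.13 ± 0.14). Floral repressors fell in 8 of 22 (11, with 1 higher, adjusted over the list alone; adjusted p = 0.00177, adjusted p = 0.626 with an estimated correlation), among them TOE1 (Aa_G234670, −1.72 ± 0.16). Floral integrators and age pathway rose in 4 of 10 (adjusted p = 0.0111, adjusted p = 0.644 with an estimated correlation), floral identity in 3 of 6 (adjusted p = 0.0375, adjusted p = 0.644 with an estimated correlation), and dormancy and branching in 5 of 10 (adjusted p = 0.0199, adjusted p = 0.644 with an estimated correlation), with DRM1 (Aa_G438760) up by 3.74 ± 0.52. CUC2 (Aa_G141220) fell by 1.00 (SE 0.18). CLV3 (Aa_G155810, −1.39 ± 0.49, adjusted p = 0.0415) lost its call under 8 alternatives, including without SAM stage 2 replicate 2 or 3 or SAM stage 3 replicate 1 or 2, with adjusted p up to 0.179. In all 5196 genes passed in SAM, 2553 higher and 2643 lower, and on TPM with a pseudocount of 1 there were 1670 higher and 3484 lower. Both tissues shared 909 rises and 907 falls, where chance gives 261 and 318, and the step differed between tissues for 997 genes. The gene paired with VIN3 (Aa_G183140), which acts in vernalization, passed in neither tissue. It is described as vernalization insensitive 3-like, so the symbol may belong to a close relative, and the response of VIN3 itself is not settled. Of the 6 vernalization genes tested, 1 passed in AB and 2 in SAM in this step. At stage 1 the list had 1 of 6 higher and 2 lower in AB (1 and 3 adjusted over the list alone). From stage 3 to 4 it had 3 higher and 2 lower in AB. Camera called the vernalization list in no comparison.

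Part of the genes described as heat shock rose in the cold. In this group, chosen after its values were seen, 24 rose, 8 fell and 71 did not pass in AB from stage 2 to 3, while 29 rose, 11 fell and 63 did not pass in SAM (medians of all of them 0.156 and 0.169). In both tissues 19 rose. A heat shock protein gene (Aa_G318690) rose at least 830-fold in SAM, to 46.4 ± 52.4 CPM (n = 3 and 3, edgeR adjusted p = 0.00476), a call lost with limma-voom, where adjusted p was 0.462 (alternatives from 1.06e-09). A small heat shock gene (Aa_G831180) went from 2 counts to 40.1 ± 34.4 CPM in AB (adjusted p = 0.00531), lost with limma-voom and with AB of these stages alone, where adjusted p reached 0.485 (alternatives from 1.93e-08). Replicate 1 of stage 3 was lowest in both tissues, at a mean log2 CPM of 2.77 in AB and 2.53 in SAM over the 19 genes, against 5.26 to 5.94 and 5.81 to 6.92 in the others.

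**Figure D3:**
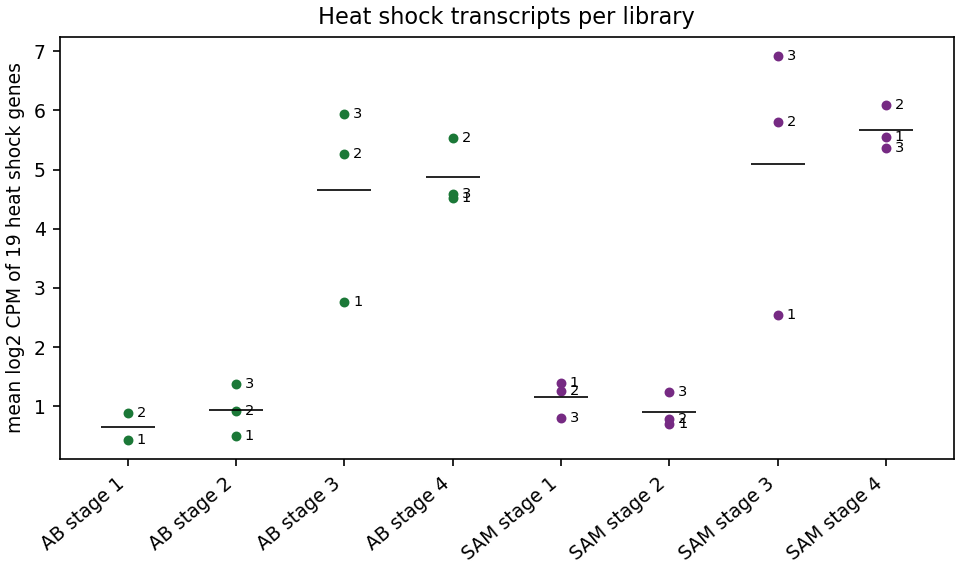
Points are the mean log2 CPM (y axis) of the 19 heat shock genes chosen for their rise in both tissues from stage 2 to 3, in each library by group (x axis), with replicate numbers beside them and a line at the group mean. Libraries of stages 1 and 2 lie between 0.43 and 1.38, and those of stages 3 and 4 between 2.53 and 6.92.

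**Figure D4:**
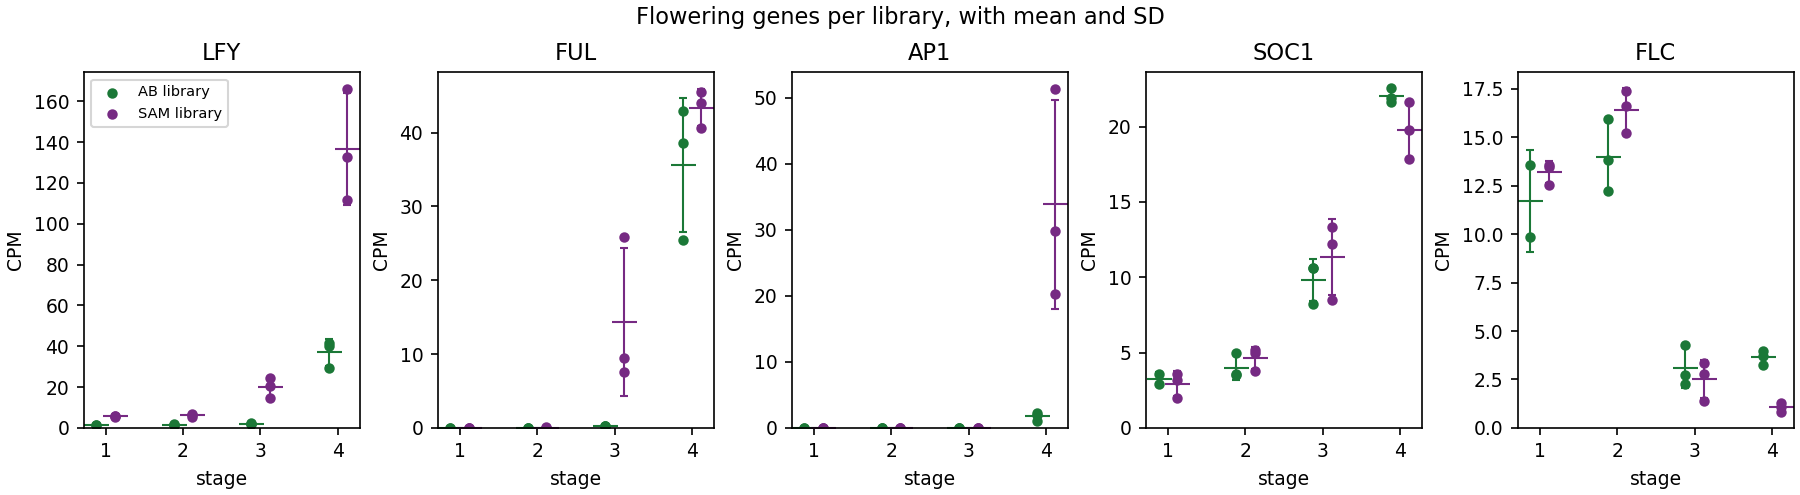
Points are the CPM of each library and lines the mean ± SD by stage (x axis) for LFY, FUL, AP1, SOC1 and FLC in AB and SAM. LFY reached 37.0 CPM in AB and 137 in SAM at stage 4, and FLC fell from 14.01 to 3.1 CPM in AB between stages 2 and 3.

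From stage 3 to 4, with longer cold, some flowering genes rose in AB. LFY (Aa_G61540) rose by 4.13 ± 0.22 (SE, n = 3 and 3, 2.11 ± 0.256 to 37.0 ± 6.63 CPM, edgeR adjusted p = 4.13e-10), FUL (Aa_G862480) by 7.25 ± 0.61 and SPL4 (Aa_G381970) by 7.55 ± 0.79. SEP4 (Aa_G675730) rose at least 51.4-fold. AP1 (Aa_G283230) rose at least 25.7-fold (adjusted p = 0.00212), a call lost with DESeq2, where adjusted p was 0.212 (alternatives from 1.34e-08). LOB (Aa_G320940), MAX3 (Aa_G175240) and DRM1 (Aa_G430660) fell by 3.55 (SE 0.23), 5.63 (SE 0.67) and 2.97 (SE 0.45).

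By list in AB from stage 3 to 4, DNA replication rose in 14 of 17 (median 0.73, camera adjusted p = 2e-05, adjusted p = 0.613 with an estimated correlation), including MCM3 (Aa_G206370, 0.77 ± 0.10). Leaf polarity and growth rose in 12 of 20 (13 adjusted over the list alone; adjusted p = 0.000319, adjusted p = 0.613 with an estimated correlation), including ETT (Aa_G305810, 0.80 ± 0.09). Floral identity rose in 4 of 6 (adjusted p = 0.000730, adjusted p = 0.613 with an estimated correlation) and floral integrators and age pathway in 6 of 10 with 1 lower (adjusted p = 0.0146, adjusted p = 0.644 with an estimated correlation). Floral repressors fell in 12 of 22 and rose in 3 (adjusted p = 0.00575, adjusted p = 0.644 with an estimated correlation), including MAF3 (Aa_G720620, −2.63 ± 0.16). Dormancy and branching fell in 8 of 10 and rose in 1 (adjusted p = 0.0111, adjusted p = 0.644 with an estimated correlation), and abscisic acid genes fell in 11 of 17 and rose in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.0202, adjusted p = 0.644 with an estimated correlation). In the auxin list 8 of 23 rose and 9 fell (8 and 10 adjusted over the list alone), and MP (Aa_G329270), an auxin response factor, rose by 1.60 ± 0.11.

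Of all genes in AB from stage 3 to 4, 10121 passed, 4932 higher and 5189 lower. SOC1 (Aa_G15970, 1.17 ± 0.18), RAX1 (Aa_G583140, 1.65 ± 0.29), LAS (Aa_G193190, 0.84 ± 0.23) and VIN3 (Aa_G183140, 0.32 ± 0.07) rose. STM (Aa_G408930, 0.40 ± 0.12, adjusted p = 0.00716) lost its call without AB stage 3 replicate 1, where adjusted p was 0.0563 (alternatives from 0.00159). FLC (Aa_G579940, 0.23 ± 0.24), WUS (Aa_G197460, 0.36 ± 0.30), CUC2 (Aa_G141220, 0.42 ± 0.18) and CLV3 (Aa_G155810, 0.40 ± 0.48) did not pass.

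In SAM from stage 3 to 4, AP1 (Aa_G283230) rose at least 509-fold, to 33.8 ± 15.9 CPM (n = 3 and 3, edgeR adjusted p = 0.000385), a call lost with DESeq2 and with SAM of these stages alone, where adjusted p reached 0.0983 (alternatives from 8.16e-12). SEP4 (Aa_G675730) rose by 5.83 ± 0.45 (SE) and LFY (Aa_G61540) by 2.78 ± 0.17. The repressor MAF3 fell by 1.91 (Aa_G720620, SE 0.14) and 4.06 (Aa_G585310, SE 0.53), and an AP2-like gene described as BBM (Aa_G192860) fell by 4.79 (SE 0.41). MP (Aa_G329270) rose by 0.88 ± 0.11. FUL (Aa_G862480, 1.62 ± 0.36, adjusted p = 0.0168), SOC1 (Aa_G15970, 0.81 ± 0.18, adjusted p = 0.00611) and FLC (Aa_G579940, −1.24 ± 0.27, adjusted p = 0.00612) lost their calls without SAM stage 3 replicate 1, and FUL also without SAM stage 4 replicate 3. FUL and FLC lost theirs with SAM of these stages alone as well, and adjusted p reached 0.144, 0.0505 and 0.0651 in turn (alternatives from 5.95e-06, 0.000369 and 0.000525). WUS (Aa_G197460, 1.20 ± 0.32, adjusted p = 0.0219) lost its call without SAM stage 3 replicate 1 or 2 or SAM stage 4 replicate 2 or 3, with adjusted p up to 0.129.

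By list in SAM from stage 3 to 4, floral identity rose in 5 of 6 and fell in 1 (camera adjusted p = 5.27e-09, adjusted p = 0.0841 with an estimated correlation). Floral integrators and age pathway rose in 6 of 10 and fell in 1 (adjusted p = 0.00237, adjusted p = 0.613 with an estimated correlation). Floral repressors fell in 9 of 22 (10 adjusted over the list alone; adjusted p = 0.000123, adjusted p = 0.613 with an estimated correlation). Auxin rose in 6 of 23 and fell in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.00200, adjusted p = 0.613 with an estimated correlation), and leaf polarity and growth rose in 3 of 20 (9, with 1 lower, adjusted over the list alone; adjusted p = 0.00354, adjusted p = 0.644 with an estimated correlation). Cold acclimation rose in 3 of 10 (7 adjusted over the list alone; adjusted p = 0.00984, adjusted p = 0.613 with an estimated correlation) and shoot epidermis markers in 3 of 7 (6 adjusted over the list alone; adjusted p = 0.00326, adjusted p = 0.614 with an estimated correlation), with the epidermal gene ATML1 (Aa_G257080) up by 0.50 ± 0.11. In all 1965 genes passed, 1100 higher and 865 lower, and on TPM with a pseudocount of 1 there were 1209 higher and 595 lower. Without SAM stage 3 replicate 1 or 2 or SAM stage 4 replicate 2 or 3 the count was 1052, 1152, 1203 and 1098.

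The step from stage 3 to 4 differed between tissues for 6389 genes, 3149 with a higher and 3240 with a lower change in AB. LFY (Aa_G61540) rose more in AB by 1.35 ± 0.28 (edgeR adjusted p = 0.00144), FUL (Aa_G862480) by 5.63 ± 0.77, and FLC (Aa_G579940) differed by 1.47 ± 0.36 (adjusted p = 0.00484). SOC1 (Aa_G15970) did not differ past the threshold (0.36, adjusted p = 0.295). Of the 3899 genes higher in AB at stage 1, 2431 fell in AB from stage 3 to 4, where chance gives 945. In the authors' deposited comparisons the counts at a false discovery rate of 0.05 were 340 for AB stage 1 to 2, 8139 for AB stage 3 to 4, 1187 for SAM stage 1 to 2 and 1619 for SAM stage 3 to 4.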

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

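Of the tests in this part, all but the test of wounding, the interaction and the counts of other splits were chosen only after the result was seen, and for the first and second patterns some took the place of earlier ones, among them a test of replicate spread and a test of the heat shock rise on genes chosen for it.

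Few genes differed between AB and SAM at stage 4, 743 by edgeR against 9460 at stage 3. Of SAM at the 4 stages, that of stage 4 was closest to AB stage 4, yet 743 genes still differed, which argues against AB stage 4 being mislabelled SAM of any of these stages. SAM tissue making up most of the AB RNA is argued against by the 167 genes that passed the threshold at least 2-fold lower in AB. A mislabelled SAM of another age stays open. Of the 393 genes at least 4-fold higher in AB at stages 1 to 3, 11.96% had all AB stage 4 libraries above all SAM stage 4 libraries, where chance gives 5%. Against it run the 94 genes that passed as higher in AB at each of the 4 stages, though a SAM of unknown age has no known profile. A smaller share of SAM tissue would by itself leave the 1269 genes at least 2-fold higher in AB at stages 1 to 3 still higher, if the buds kept that profile, but their median went from 2.97 at stage 3 to −0.0123 at stage 4. Such a share beside a change in the buds stays open. AP1, at 1.74 CPM against 33.8, would limit it to 5.16%, unless the SAM carried in held less AP1 than these libraries (20.3 to 51.3 CPM). A real approach of the bud to the SAM after 7 weeks of cold could also account for it and was not tested.

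Of the transcripts described as heat shock, 19 rose from stage 2 to 3 in both tissues, unequally between replicates, with mean log2 CPM of 2.77, 5.26 and 5.94 in AB and 2.53, 5.81 and 6.92 in SAM at stage 3. Wounding at dissection was not settled. Deviations of the wounding and heat shock scores from the group means over 12 libraries gave Pearson r = −0.0210 (two-sided permutation p = 0.983 over 1296 permutations, Spearman rho = −0.161, permutation p = 0.711, r = −0.31 without the 2 farthest libraries, 1 relation tested). No relation was seen between replicates, but 12 libraries are too few to exclude one. Wounding shared by a whole group drops out of such deviations. A rise carried by one library per group is argued against, since 6 of the 6 stage 3 libraries lay above the highest library of stage 1 on genes chosen without the library scored (the lowest was SAM replicate 1, at 2.32 against 1.33). A harvest shared by equally numbered AB and SAM libraries may account for the unequal levels. The pairing by number ranked 2 of 36 possible pairings, but the rank includes the stage 3 scores that raised this explanation, so it is not separate support. Cold itself, as named by the design, stays open and was not tested apart from the harvest.

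At stages 1 to 3 most differences of at least 2-fold were higher in AB (84.6%, 80.8% and 84.0%). Fewer reads in AB are argued against, since with all libraries thinned to 1 depth the lowest of these shares was 80.1%, and so is a batch shared by all AB libraries, since 15.1% of the genes 2-fold higher at stages 1 to 3 were so at stage 4. Leaf mesophyll cells are argued against by the photosynthesis markers, whose median log2 difference over the 4 stages was −0.43. Vascular cells cannot be told apart from the bud itself, since the vascular markers went both ways (median 0.0666). A true difference between the tissues may account for the pattern and stays open, untested.

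The interaction of tissue and stage passed for 7295 genes, so that the AB and SAM difference changed with stage. The steps of the 2 tissues differed for 21 genes from stage 1 to 2, for 997 from stage 2 to 3 and for 6389 from stage 3 to 4. The smallest interaction p-values by edgeR with Benjamini-Hochberg adjustment were 3.56e-08 for an NHL repeat gene (Aa_G189610), 4.18e-08 for a kinase gene (Aa_G375490), 4.18e-08 for a gene described as SHI-related 7 (Aa_G526710), 4.33e-08 for Aa_G756660 and 8.13e-08 for ATH1 (Aa_G58550). Among list members they were 3.53e-07 for GA2OX (Aa_G655020), 1.94e-06 for ABCB1 (Aa_G231880) and 3.16e-06 for a gene described as CLV1 (Aa_G590900). Next came 4.73e-06 for CKX (Aa_G198500), 5.45e-06 for LOB (Aa_G320940) and 7.05e-06 for CYCD3 (Aa_G97330). Then followed 7.27e-06 for ARR5 (Aa_G762130), 7.73e-06 for ARR5 (Aa_G561390) and 8.50e-06 for CKX7 (Aa_G9070).

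Other splits of the libraries were counted. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05, with 1 split as large in each, the real one. The real values and the highest of the other splits were 8014 and 0 for AB against SAM at stage 2, 9460 and 1 at stage 3, 743 and 1 at stage 4, 4764 and 0 for AB stage 2 to 3, 10121 and 2 for AB stage 3 to 4, 1623 and 13 for SAM stage 1 to 2, 5196 and 0 for SAM stage 2 to 3, and 1965 and 2 for SAM stage 3 to 4. Chance is argued against for the mean of 4 stages. There 1 of 100 splits with tissue labels shuffled within stages, the real one, reached 11320 genes, and the highest other was 7025. For the interaction 1 of 100 such splits, the real one, reached 7295, and the highest other was 6112. The shuffles also break up a tissue difference that all stages share, so they cannot decide on chance for the interaction.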

How the results depend on the processing

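The block fitted to 6 libraries, thinning, and leaving out the shallowest and deepest libraries were chosen only after seeing the data. Of 852 named results, 766 were called and none was reversed under any alternative, and 172 calls were lost without 1 library. With a 2-fold minimum, which by construction keeps fewer genes, AB against SAM at stages 1 to 4 gave 2590, 2586, 2742 and 269 genes, the mean of 4 stages 2106, AB stage 1 to 2, 2 to 3 and 3 to 4 gave 98, 1091 and 2734, and the SAM steps 353, 1385 and 679. DESeq2 gave 1140 for stage 4 and 405 for AB stage 1 to 2, limma-trend on TPM with a pseudocount of 1 gave 407 for AB stage 1 to 2, and the groups compared alone gave 1465 for stage 4, 140 for AB stage 1 to 2 and 2765 for AB stage 2 to 3, where the cause was not tested. With an estimated correlation 0 of 253 list tests and 0 of the marker list tests were called (14 of the 253 at an unadjusted p under 0.05), against 54 list tests with the preset one, and 58 with the replicate block; the cause was not tested. Without each library in turn, which leaves fewer samples, AB against SAM ran from 4347 (without AB stage 1 replicate 2) to 6623 at stage 1, 6833 to 7273 at stage 2, 7283 to 9408 at stage 3 and 373 (without AB stage 4 replicate 2) to 590 at stage 4. The mean of 4 stages ran from 10117 to 11439 and the interaction from 5536 to 7773. AB stage 1 to 2 ran from 29 (without AB stage 1 replicate 1) to 233, AB stage 2 to 3 from 3383 to 4129 and AB stage 3 to 4 from 8116 to 9967. SAM stage 1 to 2 ran from 554 (without SAM stage 1 replicate 1) to 1745, SAM stage 2 to 3 from 3661 to 4824 and SAM stage 3 to 4 from 1052 (without SAM stage 3 replicate 1) to 1831. Where AB stage 1 was left with 1 library, it was assumed to vary like the other groups. Of the named results, DESeq2 left 831 on the same side of the threshold, limma-voom 792, RLE 844, no filter 808 and thinning 816. Depth limits genes near the floor, where a fold is only a lower bound.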

Other observations

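The families, the comparisons across stages and the test of lag, which took the place of an earlier one, were chosen only after the result was seen. Genes sharing a description showed groups that the lists did not cover. All 21 tested SAUR-like auxin-responsive genes were higher in AB at stage 1, 18 at stages 2 and 3, and 17 fell in AB from stage 3 to 4 (camera adjusted p = 1.08e-10 at stage 1, adjusted p = 0.294 with an estimated correlation). Of 123 TIR-NBS-LRR disease resistance genes, 63 were higher and none lower in AB at stage 1, while 53 fell and 2 rose in AB from stage 2 to 3 and 60 fell and 3 rose from stage 3 to 4 (adjusted p = 1.95e-08 at stage 1, adjusted p = 0.294 with an estimated correlation). Of 15 pectate lyase genes, which loosen cell walls, 13 were higher in AB over the mean of stages (adjusted p = 2.85e-05, adjusted p = 0.294 with an estimated correlation).

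From stage 3 to 4 in AB, 132 of 391 pentatricopeptide repeat genes rose and 9 fell (camera adjusted p = 4.05e-06, adjusted p = 0.370 with an estimated correlation), and 9 of 11 histone H2A genes rose and 1 fell (adjusted p = 0.00110, adjusted p = 0.393 with an estimated correlation). At stage 4, 8 of 21 DOF zinc finger genes were lower in AB and 1 higher (adjusted p = 7.8e-06, adjusted p = 0.294 with an estimated correlation). Of 1463 such family tests, 224 were called with the preset correlation and 0 with an estimated one, where 142 of the 224 had an unadjusted p under 0.05. On TPM with a pseudocount of 0.1 the median log2 difference of all genes was −0.0763 in SAM stage 2 to 3 and 0.0672 between AB and SAM at stage 3, against −0.00439 and −0.00631 by edgeR on counts.

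Across stages, AB stage 4 differed from SAM stage 3 in 2457 genes and from SAM stage 4 in 743, while AB stage 3 differed from SAM stage 3 in 9460. Circadian clock genes had mean log2 CPM of 4.09, 4.67 and 4.91 in the AB stage 3 libraries and 3.87, 4.53 and 4.80 in those of SAM stage 3. At stage 4 they had 4.62, 4.85 and 4.41 in AB and 4.57, 4.79 and 4.35 in SAM. In both tissues the heat shock score, too, was lowest in replicate 1 at stage 3 and highest in replicate 2 at stage 4. Whether a shared harvest lies behind both was not tested. From stage 3 to 4, 3 of 7 clock genes passed in AB and 2 of 7 in SAM by edgeR.

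A hypothesis was that stage 4 buds may lag behind the SAM in the same change. Over 679 genes that changed at least 2-fold in SAM from stage 3 to 4, AB stage 4 lay at a median of 0.688 of the way from SAM stage 3 to SAM stage 4 on the log2 scale (quartiles 0.412 and 0.926). Genes chosen for that change can place any library below 1. With genes and scale taken without SAM stage 4 replicate 1, 2 or 3, the replicate left out lay at a median of 0.738, 0.941 and 1.04, and the highest AB library at 0.680, 0.782 and 0.757. The AB libraries lay lower each time, with the smallest difference (−0.0574) without SAM replicate 1. A lasting difference between the tissues could also place AB lower, and it cannot be told apart from a lag here. FUL lay at 0.82, AP1 at 0.48 and LFY at 0.33. SOC1 lay at 1.20, but it did not pass between AB and SAM at stage 4, so it is not told apart from 1. FLC, at −0.55, lay outside the range from SAM stage 3 (0) to SAM stage 4 (1), so a lag may leave FLC aside.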
